A study of Mus musculus and Rattus norvegicus with 26 samples.

How the data were processed

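Trophoblast stem cells of mouse and rat were measured by ChIP-seq for 5 histone marks, in mouse also for 3 transcription factors, and by 3SEQ for RNA, in 26 samples. The ChIP and input libraries were not processed again, and input read counts were not used here. Per the submitters' processing notes, the tools were CASAVA 1.5, BWA 0.9.6, SAMtools and MACS2 2.0.9 for ChIP, and CASAVA 1.5 and Bowtie 0.12.7 for RNA, on the genome builds mm9 and rn4. The notes gave neither settings nor thresholds. Each of the 13 deposited peak lists holds positions and a score per peak that the authors computed; what the score is relative to was not stated, so it served only to rank peaks within a list. The RNA tables hold raw counts per 3′ end region as deposited by the authors, not normalised, for Ensembl genes and for regions with no gene name. Whether the authors pooled the paired-end runs with the others of the same target was not stated.

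Samples were grouped by species and target as the labels give them, which made 17 groups. The 2 mouse count columns were treated as runs of 1 sample, since their numbering did not match the sample labels, and their mean was used. In the rat table, 1 count column was not used, because its replicate number matched no sample. The mouse columns held 5847895 and 4934962 counts and the rat column 10812742. Regions with no gene held 2.94% and 2.72% of the mouse counts and 5.20% of the rat counts. They were kept out of the library totals, so counts-per-million values (CPM) were taken over gene counts. CPM were at first taken over all regions and were changed to gene counts, which the plan had named, after the levels had been seen. Mouse gene names came from matching Ensembl identifiers to a reference table, which named 9694 of 9947 genes, and positions in that table were not used because they belong to another build. Rat identifiers had no names, so no rat gene was matched to a mouse gene.

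Peak lists were compared within a species by overlap of at least 1 bp, with positions given from base 1. The chance level of an overlap was the mean of 1000 circular shifts of a list along its chromosomes, and a fold is the observed share over that mean. Factor sites were the merged peaks of Cdx2, Eomes and Elf5. Enhancer-type H3K27ac peaks overlapped H3K4me1 and not H3K4me3, promoter-type peaks overlapped H3K4me3, and bivalent H3K4me3 peaks overlapped H3K27me3. Chromosome extents were the span of all peaks of a species on a chromosome. Shares carry 95% Wilson intervals, which treat peaks as independent and cover counting error only. With 1 peak list or RNA library per group, no replicate spread, test between species or p-value was computed.

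The level of each of 15 gene lists, with 216 symbols in all, was set against 10000 random lists of as many genes, by the median CPM percentile of the members among listed genes and not by their median CPM, which can differ in lists with an even number of members. The lists, the comparisons, and the rule for named genes were chosen before the data were examined. Some lists hold older symbols beside current ones of the same gene, so list sizes count symbols and not genes. The rule named the 10 most abundant genes of each library, up to 4 members of each list, and always Cdx2, Eomes and Elf5. Of the 10 rat entries only the 2 highest were printed, since rat identifiers had no names. Its parts that rest on a ratio of mouse to rat could not be applied, so the members named were the highest of each list. Other genes in the text were named by position next to a region or site, and after their values had been seen. The distance of gene 3′ ends to factor sites, marks by expression quartile, sites by combination and by score quartile, the densities of single autosomes, and the regions with no gene were added after the data had been seen. For distances to sites, 7 sets of sites and 3 distances of 20, 50 and 100 kb were computed for all 15 lists.

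Alternatives were an overlap of at least 50% of the shorter peak, the top-scoring 50% of each list, peaks widened by 500 bp on each side, local shifts of 50 to 500 kb, equal numbers of top-scoring peaks in both species, numbered chromosomes and the X only, and peaks per Mb in place of bases covered. Alternatives added after the data had been seen were sites and peaks outside the repressive marks, other distances and site sets for the trophoblast stem cell genes, single count columns, and CPM over all regions. The comparison of mouse and rat expression and of expression near promoters was left out, as it needs rat gene names and promoter positions on the same builds.

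The methods were tested on simulated data. Independent lists made with a fold of 1 gave 0.983 with whole-chromosome shifts and 0.980 with local shifts, and planted overlaps of 21.9% and 20.7% were recovered. An X ratio made as 5 was recovered as 4.94, and Wilson intervals at 650 sites held the true share in 93.8% of draws. Random gene lists had a mean percentile of 50.9, and a list with 5 of 14 genes planted near sites reached 99.7. The simulated lists were enlarged once because small ones were noisy. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.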

Results

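Trophoblast stem cells, the self-renewing precursors of the placental trophoblast, were profiled in mouse (strain 129/Sv) and rat (strain HSD). Chromatin immunoprecipitation and sequencing (ChIP-seq) mapped 5 histone marks in both species: H3K4me1, H3K4me3 and H3K27ac, which are usual at enhancers, promoters and active elements, and H3K27me3 and H3K9me3, which are usual in repressed chromatin. In the mouse it also mapped Cdx2, Eomes and Elf5, transcription factors of the trophoblast lineage. RNA was measured by 3SEQ, which counts reads at the 3′ ends of polyadenylated transcripts. The 26 samples, 16 of mouse and 10 of rat, fell into 17 groups of 1 species and 1 target each. Of these groups, 9 held 2 samples and 8 held 1. The groups comprised 20 ChIP samples, 4 input samples and 2 RNA samples, and the ChIP groups gave 13 peak lists, 8 of mouse and 5 of rat. The other sample of a pair was a paired-end record that referred to the same list, so each target had 1 list per species and no spread between replicates could be measured. The number of reads behind each peak list was unknown. The mouse RNA table held 5847895 and 4934962 counts in 2 columns, over 14006 3′ end regions. The rat RNA table held 10812742 counts in the column used, over 18493 regions. All intervals below are 95% Wilson intervals, which cover counting error only and treat peaks as independent.

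Which parts of the genome each mark and factor occupied was described by the peak lists themselves. In the mouse, Eomes had 45730 peaks, Elf5 34751 and Cdx2 11451, with median lengths of 261, 243 and 240 bp. H3K4me1 had the most mouse peaks, 79756, which covered 223 Mb. H3K27ac had 39072 peaks over 116 Mb in mouse and 7365 over 5.55 Mb in rat, a ratio of 20.8 in bases covered. H3K27me3 had 30295 peaks over 18.99 Mb in mouse and 2957 over 1.52 Mb in rat. H3K9me3 had 62509 peaks over 78.3 Mb in mouse and 10762 over 8.13 Mb in rat. The lists were nearer in size for H3K4me3, with 19818 mouse peaks over 41.3 Mb and 17358 rat peaks over 32.9 Mb, and for H3K4me1, with 60377 rat peaks over 126 Mb. With the top-scoring 50% of the list, rat H3K27ac covered 3.50 Mb. With the depth of each library unknown, the sizes were not read as how much of either genome carried a mark.

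Single regions stood out by length (mouse positions on build mm9, rat positions on rn4, from base 1). The longest mouse H3K4me1 peak spanned 157197 bp on chromosome 7 (119824761 to 119981957). The next spanned 104376 bp on chromosome 15 (61868684 to 61973059), 46.8 kb from the 3′ end of Myc, a growth-promoting transcription factor. The longest mouse H3K27ac peak, 63534 bp on chromosome 14 (8734190 to 8797723), held the 3′ end of the actin-binding gene Flnb, which had 1173 CPM (counts-per-million of gene counts). Another long H3K27ac peak, on chromosome 11 (86492344 to 86551284), held the 3′ end of Vmp1, an autophagy gene with 28.1 CPM. The longest mouse H3K9me3 peak covered 27647 bp of the X chromosome (123293108 to 123320754). The longest mouse H3K27me3 peaks, of 10993 and 7900 bp, lay on chromosome 9 (3021893 to 3032885 and 2999904 to 3007803). In the rat, the longest peaks were 46820 bp for H3K4me1 on chromosome 20 (3084094 to 3130913), 23255 bp for H3K4me3 on chromosome 18 (79387050 to 79410304), 14766 bp for H3K9me3 on chromosome 15 (104481966 to 104496731) and 8675 bp for H3K27ac on chromosome 9 (74970539 to 74979213).

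How far Cdx2, Eomes and Elf5 shared their binding sites was asked by overlap of at least 1 bp. Cdx2 shared sites with both other factors: 18.9% of Cdx2 peaks (18.2 to 19.6) overlapped an Eomes peak, 15.9 times the 1.19% found when the lists were shifted along the chromosomes 1000 times. Of Cdx2 peaks, 9.78% (9.25 to 10.3) overlapped an Elf5 peak, 11.1 times the shifted level. Of Elf5 peaks, 9.27% (8.97 to 9.58) overlapped an Eomes peak, 7.81 times the shifted level. The merged lists gave 85974 sites, of which 80790 were bound by 1 factor, 4534 by 2 factors and 650 by all 3. Shifted lists gave 2.04 sites with all 3 factors on average and 7 at most. In these shifts Cdx2 and Elf5 were moved separately against Eomes, which also removed the overlaps of pairs. Whether all 3 factors met more often than their pairwise overlaps imply was therefore not tested. Sharing was higher among high-scoring peaks, with an Eomes overlap of 27.5% in the top score quartile of Cdx2 and 15.4% in the lowest. Eomes peaks overlapped Elf5 in 13.1% of the top and 4.24% of the lowest quartile. Overlap with H3K9me3 peaks was higher in the top quartile as well, at 36.2% against 29.0% for Cdx2 and 34.3% against 24.7% for Eomes. For Cdx2 and Eomes the rise was thus not particular to sites of another factor. Peaks widened by 500 bp on each side gave lower folds, 5.59 for Cdx2 in Eomes, 3.81 for Cdx2 in Elf5 and 3.07 for Elf5 in Eomes, while the top-scoring 50% of each list gave 18.4 for Cdx2 in Elf5 and 13.1 for Elf5 in Eomes. Local shifts put both Cdx2 folds level, at 10.8 in Eomes and 10.9 in Elf5. Sites with all 3 factors numbered 390 in that upper part of the lists and 416 outside the H3K9me3 and H3K27me3 peaks.

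Which chromatin the factor sites lay in was asked by overlap with the mouse marks. Pooled over combinations of factors, active marks were more frequent at sites with more factors, but combinations differed. Sites with Elf5 alone lay in H3K27ac peaks in 23.9% and in H3K4me1 peaks in 32.2%. Sites with Cdx2 and Eomes but not Elf5 had 14.4% and 10.8%, and sites with Eomes and Elf5 but not Cdx2 had 47.6% and 55.3%. H3K27ac covered 14.3% of sites with 1 factor, 34.8% with 2 factors and 64.6% with all 3 (60.9 to 68.2), against 6.18% for shifted sites with all 3. H3K4me1 covered 17.4%, 38.1% and 67.8% (64.2 to 71.3) of the same classes, against 11.9% for shifted sites with all 3. H3K9me3 also covered more shared sites, 20.1% with 1 factor, 34.9% with 2 and 34.0% with 3 (30.5 to 37.7), against a shifted level of 5.22%. H3K27me3 covered 9.24%, 18.9% and 12.3%, and H3K4me3 5.65%, 10.4% and 12.8%. For sites with all 3 factors, peaks widened by 500 bp gave folds over the shifted level of 6.32 in H3K27ac and 3.90 in H3K9me3.

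**Figure D1:**
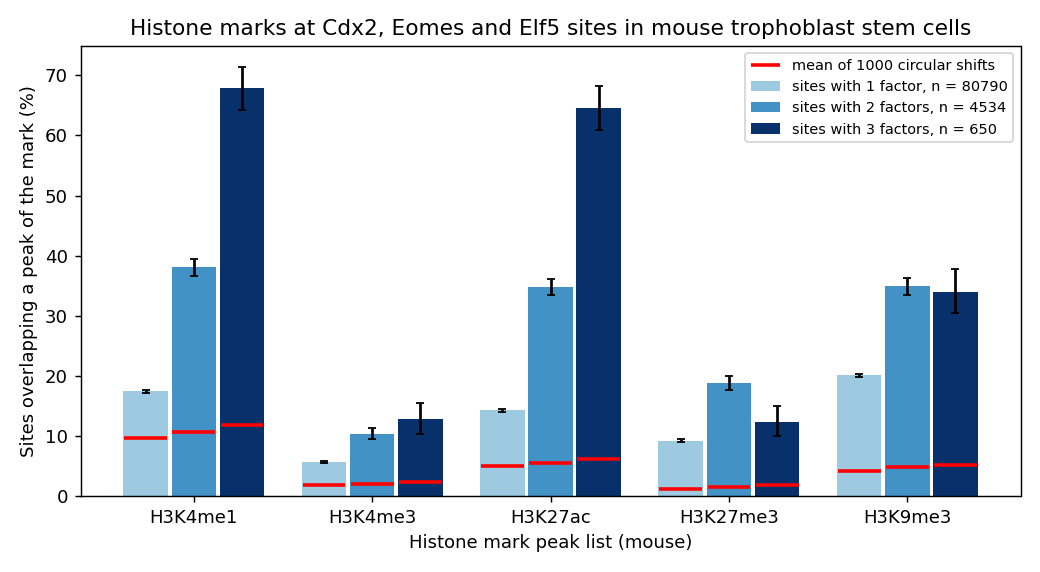
Percent of mouse factor sites that overlapped a peak of each histone mark (vertical axis), as bars for sites with 1, 2 or 3 factors, with 95% Wilson intervals and red lines at the mean of 1000 shifted lists. H3K4me1 and H3K27ac reached 67.8% and 64.6% at sites with 3 factors, while H3K9me3 stood at 34.0%.

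The factors differed in the chromatin of their own sites, a split by combination that was made after the overlaps had been seen. Of the 31041 sites with Elf5 alone, 23.9% lay in H3K27ac peaks, 7.81% in H3K9me3 peaks and 2.63% in H3K27me3 peaks. Of the 40962 sites with Eomes alone, 8.32% lay in H3K27ac, 28.0% in H3K9me3 and 13.3% in H3K27me3 peaks. The 8787 sites with Cdx2 alone had 8.25%, 26.8% and 13.7% in the same marks. Sites with Cdx2 and Eomes but not Elf5 (1516) lay in H3K9me3 peaks in 54.5% and in H3K27ac peaks in 14.4%. Sites with Eomes and Elf5 but not Cdx2 (2538) lay in H3K9me3 peaks in 23.4% and in H3K27ac peaks in 47.6%. Over all Eomes peaks, 28.7% lay in H3K9me3 peaks, 6.55 times the shifted level, and over all Cdx2 peaks 31.0% did, 7.17 times that level. Among Elf5 peaks, 26.5% lay in H3K27ac peaks, 5.06 times the shifted level. With shifts of 50 to 500 kb the fold of Eomes in H3K9me3 peaks was 4.05, and with widened peaks it was 3.51.

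Sites with all 3 factors lay in several kinds of chromatin. Of the 650 sites, 289 (44.5%) had H3K27ac and neither repressive mark, 15.8% had a repressive mark without H3K27ac and 20.2% had both, while 15 (2.31%) lay in H3K4me3, H3K27me3 and H3K9me3 peaks at once. The 3 sites with the highest summed score ranks were chromosome 9 (3023155 to 3027377), chromosome 9 (2999884 to 3005353) and chromosome 2 (98504979 to 98505520). All 3 lay in H3K4me3, H3K27me3 and H3K9me3 peaks. Of the top 10 sites 8 lay in all of these marks, and of the top 50 also 8. The 3 highest sites lay 4179, 4201 and 2897 kb from the nearest named gene end. Those on chromosome 9 overlapped the longest mouse H3K27me3 peaks. Whether sites called with active and repressive marks alike reflect factor binding was not tested. The densest windows of 200 kb were on the X chromosome (123200001 to 123400000, 6 sites), on chromosome 2 (77600001 to 77800000, 5 sites, with the 3′ ends of Cwc22 and Gm13727) and on chromosome 9 (3000001 to 3200000, 5 sites). Among the sites with H3K27ac and neither repressive mark, which were picked out after the top sites had been seen, the highest ranks were on chromosome 12 (66215829 to 66216606, 51.0 kb from the 3′ end of Fkbp3), chromosome 8 (82158076 to 82159062, 38.7 kb from Otud4) and chromosome 19 (4851109 to 4852104, 8.48 kb from Ctsf).

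How the marks combined was asked within each species, with no coordinates carried between builds. H3K27ac lay mostly with H3K4me1 in both species: 77.6% of mouse H3K27ac peaks (77.2 to 78.0) and 82.6% of rat peaks (81.7 to 83.4) overlapped H3K4me1, at 4.55 and 11.9 times the shifted levels. H3K4me3 peaks overlapped H3K4me1 in 85.7% in mouse and 74.5% in rat, at 5.50 and 8.18 times the shifted levels. H3K4me3 peaks overlapped H3K27ac in 67.5% in mouse and 16.7% in rat, where the H3K27ac list was far shorter. The folds over the shifted levels were 8.37 in mouse and 22.0 in rat. H3K27me3 peaks overlapped H3K9me3 in 32.4% in mouse and 3.55% in rat, at 6.09 and 6.44 times the shifted levels. H3K27ac peaks overlapped H3K9me3 in 7.79% in mouse, 0.880 times the shifted level, and in 4.02% in rat, 6.20 times that level. Local shifts gave folds of 2.50 in mouse and 5.94 in rat for H3K27ac in H3K4me1, and 4.01 and 6.54 for H3K27me3 in H3K9me3, and turned the mouse fold of H3K27ac in H3K9me3 to 1.97.

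**Figure D2:**
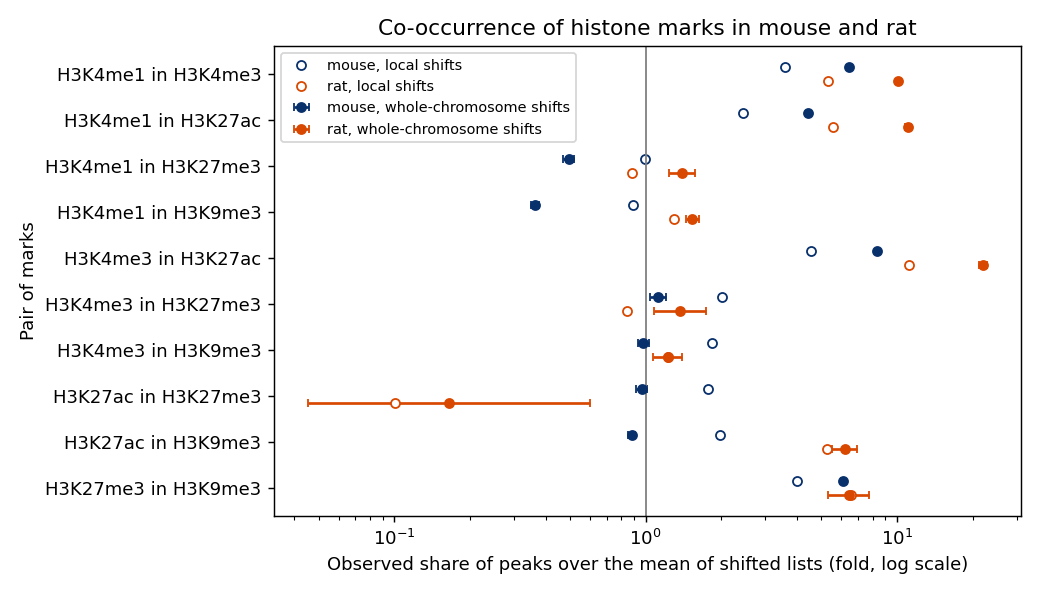
Share of peaks of one mark that overlapped another, divided by the mean share of shifted lists (horizontal axis, fold on a log scale), for mouse and rat, with filled points and 95% Wilson intervals for shifts over whole chromosomes and open points for local shifts. H3K27me3 in H3K9me3 lay at 6.09 in mouse and 6.44 in rat, while H3K27ac in H3K9me3 lay at 0.880 in mouse and 6.20 in rat.

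Chromatin classes were formed from the same lists. Enhancer-type H3K27ac peaks, with H3K4me1 and without H3K4me3, made up 46.4% of the mouse list (18141 of 39072, 45.9 to 46.9) and 46.7% of the rat list (3441 of 7365, 45.6 to 47.9). Promoter-type peaks, with H3K4me3, made up 32.2% in mouse (31.8 to 32.7) and 43.9% in rat (42.8 to 45.1). Promoter-type peaks were longer, with medians of 3310 bp in mouse and 612 bp in rat, against 1847 and 393 bp for the enhancer type. In the mouse, Elf5 peaks lay in 19.4% of enhancer-type and 26.7% of promoter-type peaks, Eomes peaks in 10.8% and 13.8%, and Cdx2 peaks in 3.56% and 3.57%. These shares were neither set against a shifted level nor matched on length. With promoter-type peaks longer, they were not read as a preference of a factor for either type. Bivalent H3K4me3 peaks, which also overlapped H3K27me3, numbered 691 in mouse (3.49%, 3.24 to 3.75) and 66 in rat (0.380%, 0.299 to 0.483), at 1.12 and 1.37 times the shifted levels. With equal numbers of top-scoring peaks the mouse enhancer-type share was 26.9%, so the near-equal shares held only for lists of unequal size. The bivalent fold fell below 1 in the top-scoring 50% of the lists, at 0.720 in mouse and 0.891 in rat, and stood at 0.926 in mouse with widened peaks and 0.844 in rat with local shifts, while local shifts gave 2.01 and equal numbers of peaks 1.89 in mouse.

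The X chromosome was compared with the autosomes by the share of bases under peaks. In the mouse, active marks were sparse on the X: H3K27ac covered 1.28% of it and 4.70% of the autosomes, a ratio of 0.271, and the ratios of H3K4me3 and H3K4me1 were 0.370 and 0.151 (0.0958 for H3K4me1 in the top-scoring 50% of its list). Mouse H3K9me3 covered 5.18% of the X and 2.88% of the autosomes, a ratio of 1.80, and H3K27me3 had a ratio of 1.74. In the rat all 5 marks were sparse on the X, with ratios of 0.351 for H3K4me3, 0.128 for H3K27me3, 0.0975 for H3K27ac, 0.0823 for H3K4me1 and 0.0317 for H3K9me3. The rat X held 17 H3K27me3 peaks and 31 H3K9me3 peaks. Among mouse factors, Elf5 had a ratio of 0.674, Cdx2 1.18 and Eomes 1.31. The sex of the cell lines was not used here.

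Single autosomes also differed, which was examined after the X had been seen. Relative to its mean density over all chromosomes, Eomes stood at 1.87 on mouse chromosome 2 and 1.53 on chromosome 8, and at 0.445, 0.409 and 0.339 on chromosomes 5, 7 and 9. Cdx2 stood at 2.03, 1.36, 0.470, 0.467 and 0.440 on the same chromosomes, and H3K9me3 at 1.76, 1.18, 0.502, 0.593 and 0.397. Elf5 stood at 1.685, 1.40, 0.614, 0.716 and 0.657, and H3K4me3 stood at 1.49, 1.02, 1.01, 1.10 and 1.08. On mouse chromosome 2 the other active marks were dense too, with H3K27ac at 1.37 and H3K4me1 at 1.24. The active marks were denser still on mouse chromosome 11, where H3K4me3 stood at 2.12, H3K27ac at 1.87 and H3K4me1 at 1.75. On rat chromosome 12 H3K4me1 stood at 2.23 and H3K4me3 at 2.20. In the rat, H3K27me3 stood at 2.84 on chromosome 9 and 3.77 on chromosome 11, while H3K27ac stood at 1.63 and 1.51, H3K9me3 at 1.85 and 0.967, H3K4me1 at 1.22 and 1.05 and H3K4me3 at 1.01 and 0.896.

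**Figure D3:**
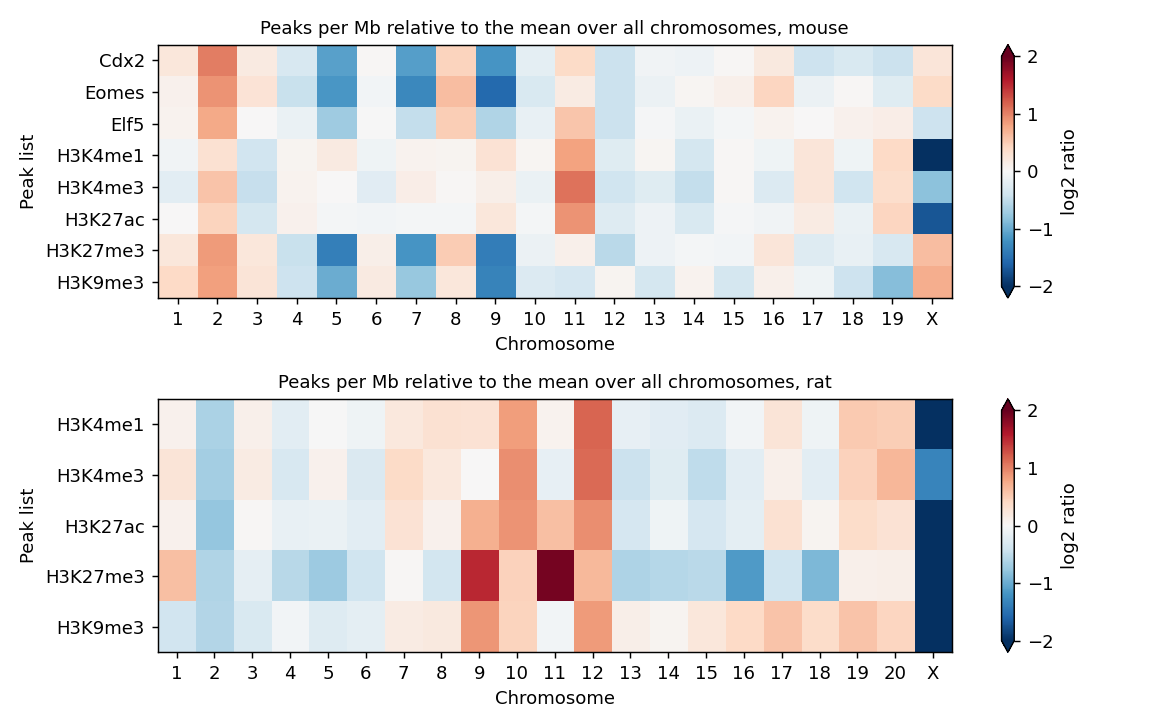
Peaks per Mb on each chromosome (horizontal axis) relative to the mean over all chromosomes, as a colour on the log2 scale, for each peak list (vertical axis) of mouse and rat. All mouse lists were dense on chromosome 2, while Eomes, Cdx2, Elf5, H3K27me3 and H3K9me3 were also sparse on 5, 7 and 9. Rat H3K27me3 was dense on chromosomes 9 and 11.

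Genes of the trophoblast stem cell programme were read from the mouse RNA counts, in which 9947 genes were listed, 9694 of them with a symbol, with a median of 16.0 CPM. Trophoblast stem cell genes stood high: 14 of 18 symbols were listed, with a median of 68.2 CPM. The 18 symbols include Tcfap2c, an older symbol of Tfap2c. Each gene was ranked by CPM among the listed genes, and the median percentile of this list, 73.8, lay above that of 97.9% of random lists of the same size. Tfap2c, a trophoblast AP-2 factor, had 1823 CPM and Esrrb, a nuclear receptor of self-renewal, 624. The immunoprecipitated factors Eomes, Elf5 and Cdx2 had 105, 64.3 and 57.0 CPM. Proliferation genes also stood high, with 11 of 13 listed, a median of 74.5 CPM and a median percentile of 75.0 (above 96.7% of random lists), and the replication helicase genes Mcm5 and Mcm2 at 639 and 335 CPM. Stress and apoptosis genes had 10 of 12 listed and a median of 89.0 CPM and a median percentile of 77.4 (above 97.8% of random lists), with Mdm2, the regulator of p53, at 1244 CPM and Atf4 at 997. Random lists were compared 15 times, with no correction, and a gene that was not listed was not shown to be silent.

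Genes of differentiated trophoblast, other lineages and signalling responses were listed in part. Of differentiated trophoblast genes 6 of 22 were listed, with a median of 49.2 CPM and a median percentile of 51.4 (above 52.3% of random lists), led by the gap junction gene Gjb3 at 852 CPM and Ascl2 at 135. Of pluripotent and epiblast genes 3 of 12 were listed (median 12.6 CPM, percentile 45.7, above 44.5%), among them Utf1 at 435 CPM and Dppa4 at 12.6. Of primitive endoderm genes 3 of 12 were listed (median 91.6 CPM, percentile 77.99, above 87.5%), led by the matrix genes Sparc at 215 and Lamb1 at 91.6 CPM. Of fibroblast and feeder genes 1 of 12 was listed, Thy1 at 6.54 CPM (percentile 31.7, above 32.0%). Of blood and endothelial genes 2 of 8 were listed (median 74.4 CPM, median percentile 43.5, above 38.2%), Pecam1 at 148 and Cdh5 at 0.897 CPM. Of the genes that respond to FGF and Activin, which were in the culture medium, 5 of 13 were listed (median 21.2 CPM, percentile 55.3, above 59.9%), with Etv4 at 74.0 and Dusp6 at 28.1 CPM.

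**Figure D4:**
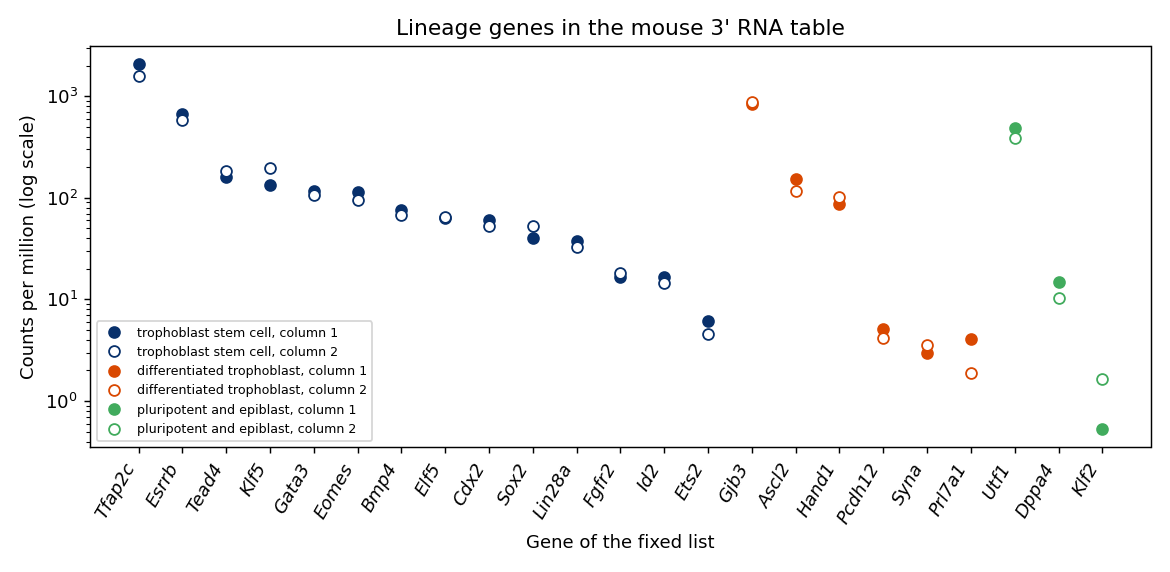
Counts-per-million (CPM, vertical axis, log scale) of the listed mouse genes of the trophoblast stem cell, differentiated trophoblast and pluripotent lists (horizontal axis), with a filled and an open point for the 2 count columns. Tfap2c and Esrrb led the trophoblast stem cell list, with means of 1823 and 624 CPM.

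Chromatin regulators spanned a wide range. All 12 genes of H3K27 methylation were listed with a median of 9.44 CPM and a median percentile of 39.2 (above 19.8% of random lists), led by the demethylase Kdm6b at 193 and the methyltransferase Ezh1 at 83.7 CPM. Of H3K9 methylation genes 14 of 16 were listed (median 20.9 CPM, percentile 54.7, above 64.4%), led by the corepressor Trim28 at 567 and the methyltransferase Ehmt2 at 268 CPM. Of H3K4 methylation and acetylation genes 16 of 22 symbols were listed (median 15.6 CPM, percentile 49.5, above 48.7%), led by Ash2l at 783 and Kat2a at 358 CPM. The 22 symbols include older symbols of genes that are also in the list by a current one. Of DNA methylation genes 8 of 10 were listed (median 14.4 CPM, percentile 47.7, above 45.1%), led by Mbd3 at 683 and Dnmt3l at 171 CPM. Of imprinted genes 13 of 21 were listed (median 44.3 CPM, percentile 67.3, above 90.5%), led by the long RNA Meg3 at 2932 and the growth factor gene Igf2 at 427 CPM. Of housekeeping genes 9 of 14 symbols, which hold Hprt and Hprt1 for the same gene, were listed (median 33.6 CPM, percentile 63.4, above 80.7%). They were led by Actb at 2760 and Rpl13a at 549 CPM.

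The most abundant mouse genes were Rps19 at 9357 CPM, Cox4i1 at 8867, Apoc1 at 8482, Krt18 at 8303, Clta at 6676, Tagln2 at 6462, Atp5d at 6393, Rack1 at 5810, Aprt at 5642 and Atox1 at 5359. Krt18 encodes a keratin of simple epithelia. The 10 highest regions held 6.60% and 7.31% of the counts of the mouse columns and 7.90% of the rat counts. In the rat, ENSRNOG00000029971, in the mitochondrial genome, had 18488 CPM and ENSRNOG00000012879 had 14321. Across genes, the Spearman correlation of the mouse columns was 0.981 and 1640 genes differed by over 1.5-fold between them. These columns were counted as 1 sample. Whether they came from separate cultures was not known, so their difference was not read as spread between cultures.

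Whether trophoblast stem cell genes lay near the shared factor sites was asked after the data had been seen. Of the 14 listed genes, 5 had a site with at least 2 factors, H3K27ac and neither repressive mark within 50 kb of the 3′ end: Bmp4 at 4.45 kb, Fgfr2 at 5.88 kb, Tfap2c at 13.2 kb, Elf5 at 17.3 kb and Id2 at 20.6 kb. Eomes, Gata3 and Cdx2 lay 57.0, 59.4 and 115 kb from such a site. Random lists held 1.29 such genes on average, and 0.62% of 10000 lists held as many. Near sites with at least 2 factors whatever the marks there were also 5 genes, as in 3.35% of random lists. Sites with all 3 factors had 1 gene, Tfap2c, as in 33.4% of random lists, and sites with Cdx2 and Eomes but not Elf5 had 0 of 14. H3K27 methylation genes had 3 (Eed, Mtf2 and Rbbp4) and imprinted genes 3 (Grb10, Igf2r and Sgce), and no other list had more than 2. This combination of sites and distance was chosen, with the results in view, from 7 sets of sites and 3 distances, so its percentage is no p-value. Distances ran from 3′ ends, since promoter positions on these builds were not used here.

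Marks around 3′ ends differed with the level of the gene, a comparison also added after the data had been seen. Expression quartiles were not matched on gene length or gene density, so the differences were not assigned to expression itself. From the lowest to the highest expression quartile of mouse genes, the share of gene ends with a peak within 10 kb went from 47.8% to 70.4% for H3K4me3 and from 64.2% to 83.1% for H3K27ac. It went from 12.7% to 5.99% for H3K9me3, from 9.09% to 3.02% for H3K27me3 and from 17.6% to 8.32% for Eomes. Elf5 stood at 27.1% and 29.6%. In the rat, the share went from 42.3% to 70.6% for H3K4me3, from 13.7% to 26.96% for H3K27ac and from 4.18% to 2.53% for H3K9me3. The 229 mouse genes within 50 kb of a site with Cdx2 and Eomes but not Elf5 had a median of 7.38 CPM, against 16.3 for the others, the widest gap among 7 sets of sites at this distance. Genes near sites with all 3 factors had a median of 13.8 CPM against 16.0, and genes near sites with any factor 15.97 against 15.98.

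**Figure D5:**
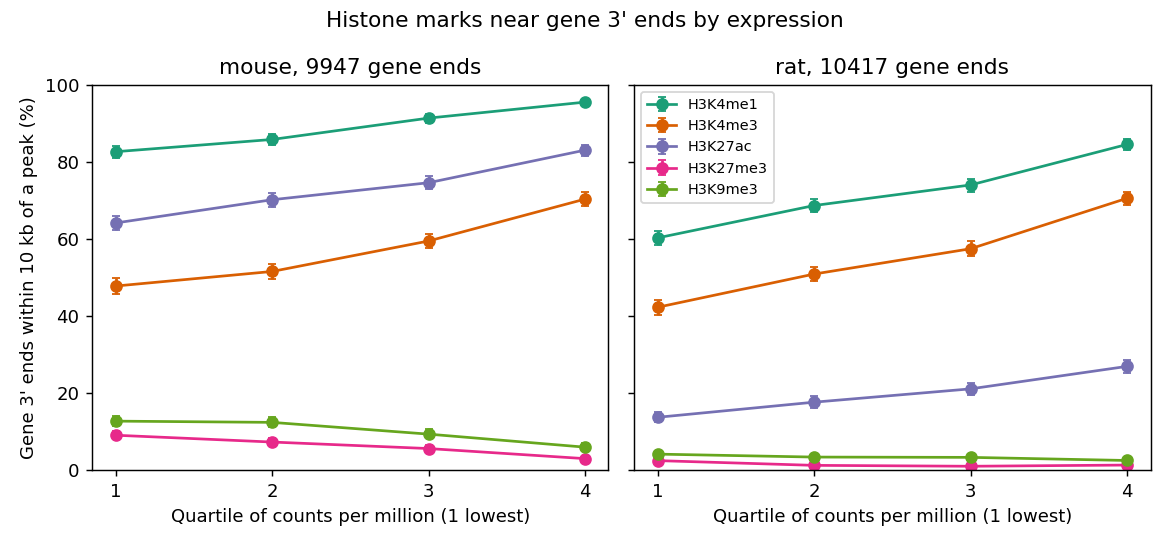
Percent of gene 3′ ends with a peak of each histone mark within 10 kb (vertical axis) by quartile of CPM (horizontal axis), in 9947 mouse and 10417 rat gene ends, with 95% Wilson intervals. H3K4me3 stood at 70.4% of mouse and 70.6% of rat gene ends in the highest quartile, while H3K9me3 lay at 5.99% and 2.53%.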

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

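For the patterns below, the tests of weak calls, copy number, regional clustering and paired-end runs were chosen after the result they measure had been seen, and the others before. Differences between species were not tested, since each had 1 list per mark.

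The X to autosome ratio of bases under H3K27me3 peaks was 1.74 in mouse and 0.128 in rat, and that of H3K9me3 was 1.80 in mouse and 0.0317 in rat, so the species lay on opposite sides of 1. Over whole-chromosome shifts, the fold of H3K4me1 peaks in H3K27me3 peaks was 0.495 in mouse and 1.40 in rat, but over local shifts it was 0.993 and 0.881, below 1 in both. The fold of H3K4me1 peaks in H3K9me3 peaks was 0.363 in mouse and 1.54 in rat, and over local shifts 0.887 and 1.297. Among RNA counts that the comparisons did not use, regions with no gene held 2.94% and 2.72% of the mouse columns and 5.20% of the rat column.

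Eomes peaks were 4.31 times as dense on mouse chromosomes 2 and 8 as on 5, 7 and 9. Weak calls were argued against, since the ratio was 5.13 in the top score quartile. Signal shared with H3K9me3 and H3K27me3 was argued against as the whole source, since the ratio was 2.97 among the 29595 Eomes peaks outside both lists, against 9.19 inside. Chromosome copy number cannot be told apart from other sources: H3K4me3 peaks per gene end gave a ratio of 1.22, above 88.7% of 116280 choices of chromosomes, which neither reached nor ruled out the level set for it. Relative densities on chromosome 2 in the top score quartile were 1.60 for H3K4me1, 1.49 for H3K4me3 and 1.35 for H3K27ac. They were 2.37 for H3K27me3 and 2.27 for H3K9me3. Over all peaks these marks stood at 1.24, 1.49, 1.37, 1.81 and 1.76. On chromosome 8 they stood at 1.04, 1.03, 1.02, 1.47 and 1.23 in that quartile. H3K4me3 stood at 1.005, 1.16 and 1.14 there on chromosomes 5, 7 and 9. These values leave copy number open. No biological explanation was tested, since the design has no group for one.

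Eomes and Cdx2 peaks lay in H3K9me3 peaks more often than shifted lists. Regional clustering was argued against as the whole source for Eomes, since the fold over local shifts was still 4.05. It was 6.55 over whole-chromosome shifts, and the shifted level rose from 4.38% to 7.09% with local shifts. Clustering over distances shorter than the local shifts was not tested. Paired-end runs cannot be told apart from other sources: Cdx2, which had no paired-end record, had a fold of 7.17, but the H3K9me3 list had such a record itself. Signal that recurs at the same loci whatever the antibody remains a candidate explanation: H3K9me3 peaks that overlapped H3K27me3 held an Eomes peak 2.05 times as often as equally long ones that did not (36.7% against 17.8%), just past the bound of 2 set before. No biological explanation was tested.

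Rat H3K27me3 peaks were dense on chromosomes 9 and 11. A few clusters were argued against, since the 5 fullest windows of 1 Mb held 11.5% of the 686 peaks there. Copy number cannot be told apart from other sources. H3K4me3 peaks per gene end on these chromosomes were 1.09 times the median of the other autosomes. They were 1.97 on chromosome 9 and 1.71 on chromosome 11, inside the range of 1.303 to 2.22 of the others. This count takes no account of peak scores. In the top score quartile, relative densities on chromosomes 9 and 11 were 1.63 and 1.51 for H3K4me1 and 1.176 and 1.1996 for H3K4me3. They were 2.15 and 2.11 for H3K27ac and 2.14 and 1.34 for H3K9me3. All were above the densities over all peaks. H3K27me3 was higher on chromosome 9 (3.399 against 2.84) and lower on 11 (3.701 against 3.77). These values leave copy number open. No biological explanation was tested.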

How the results depend on the processing

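Comparisons with sites and peaks outside the repressive marks, other distances and site sets, single count columns and CPM over all regions were chosen after the data had been seen. Of the values that answer a comparison, 23 stayed within their error or count range, 51 moved beyond it and 4 reversed, and of the other values 9 stayed, 21 moved and 4 reversed. Except where stated, the cause was not tested. Depth was unknown for the peak lists, which limits every comparison of list size.

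With at least 50% of the shorter peak shared, folds over shifted lists were 22.5 for Cdx2 in Eomes, 16.3 for Cdx2 in Elf5, 10.99 for Elf5 in Eomes, 7.43 for Eomes in H3K9me3, 5.33 (mouse) and 13.6 (rat) for H3K27ac in H3K4me1, 1.04 for rat H3K4me3 in H3K27me3, and 13.3 and 8.71 for sites with 3 factors in H3K27ac and H3K9me3. The enhancer-type share was 45.3% in mouse and 49.5% in rat.

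With the top-scoring 50% of each list the same folds were 22.5, 18.4, 13.1, 7.41, 6.08, 15.6, 0.891 (reversed), 13.3 and 7.92, and that of mouse H3K4me3 in H3K27me3 was 0.720 (reversed). Sites with 3 factors numbered 390. The enhancer-type share was 48.4% in mouse and 50.1% in rat, rat H3K27ac covered 3.50 Mb, by construction less than the whole list, and the X ratio of mouse H3K9me3 was 1.72.

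With peaks widened by 500 bp on each side, folds were 5.59 for Cdx2 in Eomes, 3.81 for Cdx2 in Elf5, 3.07 for Elf5 in Eomes, 3.51 for Eomes in H3K9me3, 3.70 (mouse) and 8.09 (rat) for H3K27ac in H3K4me1, 0.926 (reversed) for mouse H3K4me3 in H3K27me3, and 6.32 and 3.90 for sites with 3 factors in H3K27ac and H3K9me3. The enhancer-type share was 47.0% in mouse and 43.5% in rat.

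With local shifts, folds were 10.8 for Cdx2 in Eomes (10.9 for Cdx2 in Elf5), 4.05 for Eomes in H3K9me3, 2.50 (mouse) and 5.94 (rat) for H3K27ac in H3K4me1, 2.01 for mouse and 0.844 (reversed) for rat H3K4me3 in H3K27me3, and 8.69 for sites with 3 factors in H3K27ac. They reversed mouse H3K4me3 in H3K9me3 to 1.84, mouse H3K27ac in H3K27me3 to 1.77, mouse H3K27ac in H3K9me3 to 1.97 and rat H3K4me1 in H3K27me3 to 0.881.

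With equal numbers of top-scoring peaks in both species, mouse folds were 4.79 for H3K27ac in H3K4me1 and 1.89 for H3K4me3 in H3K27me3, and the mouse enhancer-type share was 26.9%. Outside the H3K9me3 and H3K27me3 peaks, folds were 19.2 for Cdx2 in Eomes, 13.0 for Cdx2 in Elf5, 10.2 for Elf5 in Eomes and 11.4 for sites with 3 factors in H3K27ac, and 416 such sites remained. As peaks per Mb, the X ratio was 0.293 for mouse H3K27ac, 1.73 for mouse H3K9me3 and 0.0474 for rat H3K9me3. The median of the trophoblast stem cell list was 68.2 CPM, and 66.3 CPM over all regions.

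Not run, as rat genes had no names, were all alternatives for mouse against rat expression: CPM over matched genes, TMM factors, median-of-ratios size factors, other count filters and another pseudocount, and, for the gene lists between species, TMM factors and a filter of at least 50 counts.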

Other observations

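All values below were chosen after the data had been seen, and no explanation was tested. Of the mouse RNA regions with no gene name, 35 of 4059 (0.862%) overlapped a Cdx2 peak by at least 1 bp. Of the 3′ end regions of genes, 5 of 9947 (0.0503%) did. The lengths of the regions were not matched. The shares for Elf5 were 1.31% and 0.915%, and those for Eomes 0.714% and 0.533%. In the top expression quartile of the unnamed regions, 28 of 1015 (2.76%, 1.92 to 3.96) overlapped a Cdx2 peak. Their median was 8.14 CPM, and the gene quartile nearest to it, with a median of 8.55 CPM, had 2 of 2487 (0.0804%, 0.0221 to 0.293). The unnamed region on chromosome 15 (18315028 to 18315245) had 48555 counts and overlapped an H3K9me3 peak, and another had 15919 counts. In the rat, the region on chromosome 4 (184112261 to 184112559) had 71651 counts.

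Mitochondrial regions held 0.141% and 0.111% of the mouse counts and 2.94% of the rat counts. A site with all 3 factors, H3K27ac and neither repressive mark lay 1.76 kb from the 3′ end of Ccdc77, a gene with 149 CPM.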
